A study of Caenorhabditis elegans with 2 samples.

How the data were processed

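Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where the HMG-11 protein lay on the genome of whole Caenorhabditis elegans. The animals were hermaphrodites at the third larval stage (L3), collected 52 h after synchronisation by starvation at the first larval stage. They carried an integrated transgene of hmg-11 with a C-terminal GFP and FLAG tag, in an unc-119 mutant background, and chromatin was sheared by sonication and precipitated with an antibody against GFP, per the labels. There were 2 biological replicates of 1 group. No untagged, input or other control library was analysed here, although the labels name a possible control experiment.

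The files were 8 peak lists, 4 on each of the genome builds ce10 and ce11. Per the labels, each build had 1 list of candidate regions for each replicate and 1 list called on the reads of both replicates together (the pooled list). It also had 1 list of peaks thresholded by the irreproducible discovery rate (IDR), a measure of how alike the ranks of regions are between lists. Each replicate or pooled list held 30000 regions, peaks and background together. The aligner, the peak caller and their versions are not given in the sources used here. The deposited signal value of each region is the authors' own peak signal, taken against a control and on a scale that is not given in the sources used here, so it was used to rank and describe regions within a list, and set side by side across lists only for the same libraries on the ce10 and ce11 builds. The deposited −log10 q-value of each region was capped at the highest value of its list, which 3637 pooled regions shared, so regions were ranked by signal. Summit positions were taken from the deposited offset within each region. Numbers of reads are unknown from these lists, so no interval below covers sequencing depth. The lists hold called regions only, and regions weaker than the 30000 listed were not seen.

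The ce11 lists were the main data. Every ce11 region ended within the length of its chromosome in the reference sequence of the same assembly (WBcel235), and genes, transcripts and exons were taken from Ensembl release 115 for that assembly. All 4037 IDR peaks were identical in position to pooled regions and were the 4037 strongest of them by signal. The IDR list therefore equals a cut of the pooled list by signal. A place in it does not establish that the replicates agreed at that region. The other 25963 pooled regions served as background, since they could have passed. Coordinates are given from 1 on ce11. No coordinate was converted between builds.

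Each summit was assigned in this order to a promoter window (1000 bp upstream to 200 bp downstream of any annotated transcript start), 5′ untranslated region, coding exon, 3′ untranslated region, other exon, intron or intergenic sequence. Distances were measured to the nearest protein-coding transcript start. A gene was counted as having a peak when its promoter window held the summit of an IDR peak. It was tested only when its window held the summit of any pooled region. The 32 gene lists were fixed by gene symbol before the data were examined. They were tested among protein-coding genes, except heterochronic genes, which were set against genes of every class because that list named miRNAs. Base composition and sequence motifs were read in the summit base and 50 bp on either side. Shares carry 95% Wilson intervals. Odds ratios carry 95% Woolf intervals and two-sided Fisher exact tests, with Benjamini-Hochberg adjustment over the lists, gene classes, chromosomes, features or motifs tested together and a threshold of 0.05. Differences in A+T content and distance were tested by two-sided permutation tests with 100000 resamples (10000 for alternatives), with bootstrap intervals from 1000 draws. Motif odds ratios were also taken within strata of 5 percentage points of A+T content (Mantel-Haenszel). Regions and genes are not replicates of the animals: their p-values measure the spread among regions or genes of these 2 libraries, neighbouring genes share windows, and the only check across animals is the comparison of the replicates.

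The genes named were those of the 30 strongest IDR peaks, the up to 4 members of each list with the strongest region, up to 4 members in order of symbol of each list with under 25 members, all members of the Hox cluster and heterochronic lists, and hmg-11, hmg-12 and unc-119. Names outside this rule are marked as chosen after their values were seen. Lists of cell type markers, other than the pharynx list, stood for tissues of the whole animal, and no cell type was called from them. The alternatives set before the data were examined were stricter overlaps, the ce10 lists, the 2018 strongest peaks, each replicate alone (its 4037 strongest regions against the rest of its list), other promoter windows, all annotated genes or shifted peaks as background, genome length or random positions as background, and other sequence windows. Further alternatives are named as added later.

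The tests were tried on simulated data first. With peaks drawn at random from the pooled list in 100 simulations, 0.433% of 3000 list tests passed the threshold. A simulated list of 72 genes given odds of 5 returned a median odds ratio of 4.98 and passed, without adjustment, in 100% of 100 simulations. These genes and their comparison genes held 1 listed region each, so genes with several listed regions were not covered. A motif given odds of 2 within A+T strata returned a median of 1.95 over 100 simulations of 30000 regions. The permutation test passed in 6% of 100 simulations of 3000 regions with no effect. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and Matplotlib 3.10.9.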

Results

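HMG-11 is a small protein of the HMGA type, whose AT-hook motifs bind the minor groove of A/T-rich DNA. Its binding was mapped by ChIP-seq against a GFP tag in whole L3 larvae of C. elegans, in 2 biological replicates of 1 group. The data are lists of called regions, with 30000 candidate regions for each replicate and for the pooled reads, and 4037 peaks that passed the IDR filter. The comparisons asked how alike the replicates were and where the peaks lay relative to genes, gene groups, chromosomes and sequence, with the other 25963 pooled regions as background.

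The strongest peak in the pooled list and in each replicate lay upstream of rpl-3, which encodes a protein of the large ribosomal subunit (chromosome III, 3867458 to 3867705, summit 260 bp upstream of the transcript start, pooled signal 529). The second strongest pooled peak lay 354 bp upstream of rpl-15 (chromosome IV, 654812 to 655053, signal 423). Its summit was also in the windows of K11H12.8 and of the snoRNA genes K11H12.12 and K11H12.13. The fifth lay in the windows of rpl-20 and Y17G9B.5 (chromosome IV, 4749955 to 4750194, signal 381). All 30 of the strongest peaks ranked among the 100 strongest regions of both replicates. The windows of these 30 held, among others, the chromatin genes pbrm-1, chd-7 and bet-2, the homeobox gene ceh-38, the autophagy gene epg-7, sec-15 of the exocyst, and tub-2. Promoter windows held 23 of the 30 summits, introns 2 and intergenic sequence 5. The 5 intergenic peaks were all on X, at 806573 to 806782 (rank 3), 13700807 to 13700960 (rank 8), 11094083 to 11094301 (rank 25), 16681982 to 16682212 (rank 27) and 1093225 to 1093405 (rank 30). Of the 30, 11 were on X.

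The replicates shared most of their strongest regions. Of the 4037 strongest regions of replicate 1, 3176 (78.7%, 95% Wilson interval 77.4 to 79.9) overlapped by at least 1 bp one of the 4037 strongest of replicate 2, against a mean of 13.0% and a maximum of 14.7% over 1000 random draws of as many regions from each list. Over the whole lists, 22035 regions (73.4%) of replicate 1 overlapped a region of replicate 2, and the Spearman correlation of their signals, taken across regions, was 0.54. That correlation was 0.68 for the matched regions among the 4037 strongest of replicate 1 and 0.038 for the matched regions among its 10000 weakest. Of the IDR peaks, 4025 (99.7%, interval 99.5 to 99.8) were listed in both replicates, 3088 (76.5%, interval 75.2 to 77.8) were among the 4037 strongest of both, and 62 (1.54%) were among the strongest of neither.

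Peaks lay mainly at promoters. A promoter window held 3046 of the 4037 peak summits (75.5%, interval 74.1 to 76.8), compared with 42.2% of the other listed regions (odds ratio 4.21, 95% interval 3.91 to 4.55). Introns held 8.0% of peak summits and 27.4% of the others (odds ratio 0.229, interval 0.203 to 0.257). Coding exons held 22 peak summits (0.54%) against 9.2% of the others (odds ratio 0.054, interval 0.036 to 0.083, adjusted p = 2.2e-121 by Fisher's exact test), and 3′ untranslated regions held 14 (0.35%) against 2.7% (odds ratio 0.126, interval 0.074 to 0.214). Intergenic sequence held 15.04% of peaks and 17.8% of the others (odds ratio 0.817, interval 0.746 to 0.896). Shares in 5′ untranslated regions and other exons did not differ past the threshold (Fisher's exact test, adjusted p = 0.63 and 0.90). With the windows of protein-coding transcripts alone, an alternative added after the data were seen, the promoter share was 60.9% of peaks and 29.2% of the others (odds ratio 3.77), and other exons, which then include exons of noncoding genes near their own starts, held 5.5% and 2.5% (odds ratio 2.29, interval 1.96 to 2.68).

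**Figure D1:**
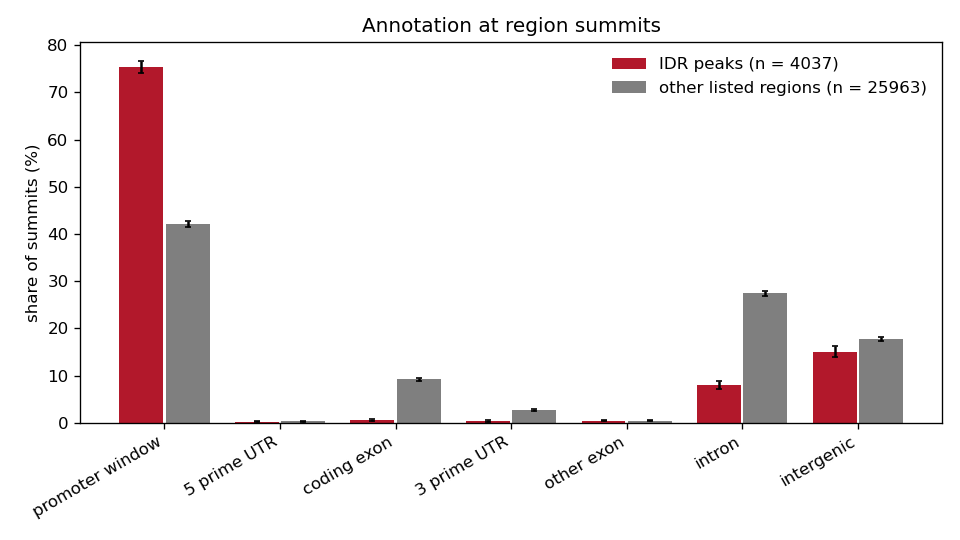
Share of summits (%, y axis) in each annotation class (x axis) for the 4037 IDR peaks and the other 25963 listed regions of the pooled ce11 list; bars show shares and error bars 95% Wilson intervals. Promoter windows held 75.5% of peak summits and 42.2% of the others, and coding exons 0.54% and 9.2%.

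Summits of peaks sat upstream of transcript starts. The median position was 233 bp upstream of the nearest protein-coding start for peaks (−233 bp, bootstrap interval −250 to −218) and −79 bp for the others (interval −96 to −59), a difference of −154 bp (permutation p = 1e-05, the smallest that 100000 resamples can give). Peaks were upstream of that start in 79.4% of cases and the others in 52.6%. Within the first 300 bp upstream lay 35.7% of peaks and 9.7% of the others. The median absolute distance was 443 bp for peaks and 1384 bp for the others. Promoters shared by genes on opposite strands were frequent among peaks: of 2458 peak summits in a protein-coding window, 712 (29.0%, interval 27.2 to 30.8) lay in windows of both strands, compared with 726 of 7594 (9.6%, interval 8.9 to 10.2) of the other listed summits (odds ratio 3.86, interval 3.44 to 4.33). This last comparison was chosen after the data were seen.

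**Figure D2:**
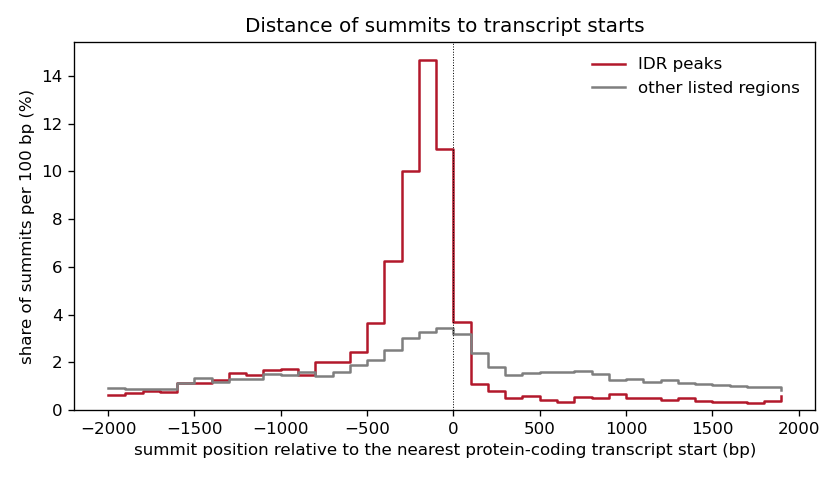
Share of summits per 100 bp (%, y axis) by position relative to the nearest protein-coding transcript start (bp, x axis; negative values are upstream) for IDR peaks and the other listed regions. Peaks gather just upstream of the start, with a median of −233 bp.

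Chromosomes held peaks in about the proportion of listed regions. X held 777 peaks (19.2%) and 18.5% of the other regions, chromosome III 766 peaks (18.97%) and 18.6%, and chromosome V 546 peaks (13.5%) and 13.9%, and no chromosome passed the threshold (odds ratios 0.94 to 1.05, smallest exact adjusted p = 0.83). Relative to chromosome length, every chromosome departed past the threshold (binomial test, adjusted p from 1.1e-32 for V to 0.017 for IV). Chromosome III had the highest density with 55.6 peaks per Mb and chromosome V the lowest with 26.1. The other listed regions also were densest on III and sparsest on V, with 351 and 173 per Mb. Peaks were more central than the other regions: the middle 50% of the chromosomes held 54.1% of peaks and 43.9% of the others (odds ratio 1.51, interval 1.41 to 1.61). Against random positions, of which 50.3% were central, the odds ratio was 1.16 (interval 1.09 to 1.24). The odds ratio for the centre was 1.796 on chromosome III, 1.78 on V, 1.65 on I, 1.49 on IV and 1.40 on II, each past the threshold, and 1.12 on X (interval 0.96 to 1.30, exact adjusted p = 0.16). Whether X differed from the autosomes in this was not tested.

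Genes of protein synthesis and respiration were at peaks more often than other genes. Of the 78 ribosomal protein genes, 72 had a listed region in the promoter window and 68 of these (94.4%) had a peak, compared with 43.0% of the other 6789 tested genes (odds ratio 22.5, interval 8.2 to 61.9, exact adjusted p = 6.1e-19). The odds ratio was 11.7 with replicate 1 alone (65 of 73) and 24.5 with replicate 2 alone (69 of 73). Besides rpl-3, rpl-15 and rpl-20, rps-1 had the next strongest peak (265 bp upstream, signal 310, rank 31). Peaks were found at 27 of 33 tested genes of the mitochondrial respiratory chain (81.8%, odds ratio 5.88, interval 2.42 to 14.3, exact adjusted p = 0.00014), with cox-5A (signal 282), cox-5B (235), atp-1 (212) and atp-2 (197) the strongest; cox-5A and cox-5B encode subunits of cytochrome c oxidase and atp-1 and atp-2 subunits of ATP synthase. Translation factors and tRNA synthetases had peaks at 36 of 52 (odds ratio 2.94, exact adjusted p = 0.0013), led by iff-2 (signal 253), ears-2 (244), eef-1B.1 (206) and eif-3.C (204). An alternative added after the data were seen counted each summit only for its nearest transcript start. Ribosomal protein genes then had a peak at 31 of 43 tested, in place of 68 of 72 (odds ratio 4.91, interval 2.51 to 9.58). The respiratory chain no longer passed (11 of 22, odds ratio 1.88, exact adjusted p = 0.40).

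Lists of 4 further functions were at peaks more often. Heat shock proteins and chaperonins had peaks at 32 of 45 tested genes (odds ratio 3.22, interval 1.69 to 6.14, exact adjusted p = 0.0013), among them cct-1 of the cytosolic chaperonin (signal 243), hsp-60 of the mitochondrial chaperonin (225), hsp-110 (230) and dnj-14 (260); the peak of hsp-110 was also that of rpn-3, a proteasome subunit on the shared window. The cell cycle and DNA replication list had peaks at 41 of 66 (odds ratio 2.14, interval 1.30 to 3.53, exact adjusted p = 0.0086). It was led by cdc-48.1 (signal 271), scc-2 (252), which loads cohesin, and the kinase genes cdk-9 (240) and cdk-7 (204). Its members were matched by symbol, so a place in it does not establish a role in the cell cycle. Chromatin and synMuv regulators had peaks at 27 of 41 (odds ratio 2.51, interval 1.32 to 4.80, exact adjusted p = 0.013), led by the SWI/SNF subunit genes swsn-7 (271) and swsn-3 (223), the acetyltransferase gene cbp-1 (243) and lin-9 (234.4). All 6 tested genes of the 9 HMG proteins had peaks (odds ratio 16.9 with 0.5 added to each count, lower bound of the interval 0.95, exact adjusted p = 0.019), among them hmg-1.2 (269), hmg-1.1 (235), hmg-6 (176) and hmg-12 (127). With the window of 500 bp on either side of the start, neither the HMG list (odds ratio 7.31, exact adjusted p = 0.11) nor the chromatin list (1.72, adjusted p = 0.26) passed. With each summit given to its nearest start, the chaperone, HMG and chromatin lists did not pass (exact adjusted p = 0.84, 0.30 and 0.098). The odds ratios there were 1.25 for chaperones (10 of 25), 9.39 for HMG proteins (2 of 2) and 2.26 for chromatin regulators (18 of 33). Over all settings the exact adjusted p of the HMG list ran from 0.00105 to 0.30, that of the chromatin list from 1.4e-08 to 0.26 and that of the chaperone list from 1.6e-11 to 0.84. Among the 2018 strongest peaks the chaperone, cell cycle and translation lists did not pass (odds ratios 2.03, 1.86 and 1.91, exact adjusted p = 0.071, 0.069 and 0.079).

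**Figure D3:**
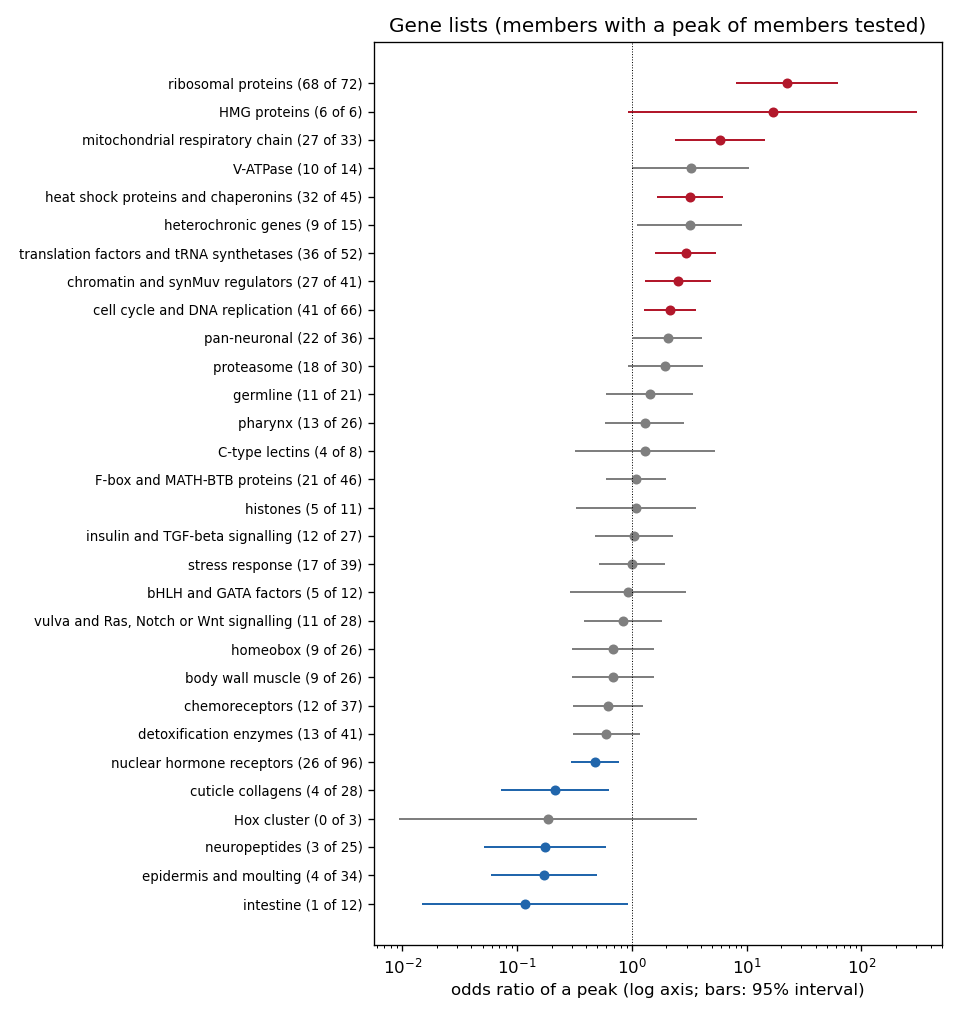
Odds ratio of having a peak in the promoter window for the members of each gene list against other tested genes (x axis, log scale; dots are estimates and lines 95% intervals; red higher, blue lower past the threshold, grey neither), with the members that had a peak and the members tested beside each name. Heterochronic genes are set against genes of every class and the other lists against protein-coding genes. Ribosomal proteins stand at 22.5 and epidermis and moulting genes at 0.17.

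Epidermis and moulting genes, cuticle collagens, neuropeptides, nuclear hormone receptors and intestinal genes were at peaks less often than other genes. Epidermis and moulting genes had peaks at 4 of 34 tested members (vab-10, ajm-1, bli-6 and grl-26; odds ratio 0.172, interval 0.060 to 0.488, exact adjusted p = 0.00089), cuticle collagens at 4 of 28 (col-185, col-38, col-71 and col-8; odds ratio 0.215, interval 0.075 to 0.621, exact adjusted p = 0.0064), and neuropeptides at 3 of 25 (ins-39, nlp-4 and flp-23; odds ratio 0.176, interval 0.053 to 0.589, adjusted p = 0.0049). Nuclear hormone receptors had peaks at 26 of 96 (odds ratio 0.477, interval 0.303 to 0.7504, exact adjusted p = 0.0051), with nhr-1 (signal 226) and nhr-255 (222) the strongest, and the call was lost with each summit given to its nearest start (exact adjusted p = 0.12). Intestinal genes had a peak at 1 of 12, at erm-1 (signal 136), while pgp-2, fat-6 and spp-28 had listed regions that were not peaks (odds ratio 0.118, interval 0.015 to 0.911, exact adjusted p = 0.041). The intestinal call was lost with replicate 1 alone (odds ratio 0.351, exact adjusted p = 0.19) and with replicate 2 alone (0.213, adjusted p = 0.062). It was also lost with either other promoter window (exact adjusted p = 0.060 and 0.27) and with nearest starts (0.30). It held in 1 of 7 other settings, against all annotated genes, where the adjusted p by Fisher's exact test was 3.2e-06. The neuropeptide call was lost with replicate 1 alone (odds ratio 0.312, exact adjusted p = 0.052). Among the 2018 strongest peaks neither the epidermal list nor the collagen, neuropeptide or intestinal list passed (exact adjusted p = 0.22, 0.076, 0.13 and 0.50). Their odds ratios there were 0.403, 0.233, 0.263 and 0.276, all still under 1. Peaks were also shifted along the chromosomes, so that genes without a listed region counted. Nuclear hormone receptors then had 1.67 times as many genes with peaks as after shifting (permutation adjusted p = 0.039). Protein-coding genes as a class had 2.77 times as many, so nuclear hormone receptors stayed below the class. The other lists of this paragraph stood at 0.18 to 0.58 times without passing.

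The other lists did not pass the threshold. Among markers of tissues, pan-neuronal genes had peaks at 22 of 36 (odds ratio 2.05, interval 1.04 to 4.01, exact adjusted p = 0.090), with egl-30 (signal 235) and syd-2 (227) the strongest. The germline list had peaks at 11 of 21 (odds ratio 1.43), with puf-9 (214) the strongest. Its members were matched by symbol, so a place in it does not establish a role in the germline. Body wall muscle genes had peaks at 9 of 26 (0.69), with unc-60 (207) and act-4 (195) the strongest. The pharynx list had peaks at 13 of 26 (odds ratio 1.30). All 13 carried the symbol pqn (13 of 23 tested pqn genes), which does not name a tissue, so this list does not stand for the pharynx. The V-ATPase had peaks at 10 of 14 (odds ratio 3.25, exact adjusted p = 0.11) and the proteasome at 18 of 30 (1.95, adjusted p = 0.18). The pan-neuronal, proteasome and V-ATPase lists passed in some settings: pan-neuronal genes with replicate 2 alone (odds ratio 2.29) and with 2000 bp upstream (4.52), the proteasome with replicate 1 alone (2.83) and with 2000 bp upstream (2.63), and the V-ATPase among the 2018 strongest peaks (4.06). Odds ratios were 1.08 for histones (5 of 11), 0.69 for homeobox genes (9 of 26), 0.93 for bHLH and GATA factors (5 of 12), 0.84 for vulval and Ras, Notch or Wnt signalling (11 of 28), 1.04 for insulin and TGF-beta signalling (12 of 27), 0.62 for chemoreceptors (12 of 37), 1.09 for F-box and MATH-BTB proteins (21 of 46), 1.30 for C-type lectins (4 of 8), 0.60 for detoxification enzymes (13 of 41) and 1.00 for stress response genes (17 of 39). Detoxification enzymes were lower past the threshold with replicate 1 alone (odds ratio 0.412), with replicate 2 alone (0.377), among the 2018 strongest peaks (0.238) and with 2000 bp upstream (0.487). Chemoreceptors were lower past the threshold with replicate 1 alone (0.382). None of the 44 major sperm protein genes and none of the 7 genes of vitellogenins and yolk had a listed region in the window. Against all annotated genes, chemoreceptors (12 of 1318, odds ratio 0.048), C-type lectins (4 of 240, 0.095) and F-box and MATH-BTB proteins (21 of 395, 0.31) were lower past the threshold, as were histones (0.373), major sperm proteins (0.064) and detoxification enzymes (0.358). In that setting the proteasome (6.86), V-ATPase (5.70), pan-neuronal (5.99) and stress response (1.94) lists were higher past the threshold. With shifted peaks, the lists above that were higher past the threshold were the proteasome (10.9 times), V-ATPase (10.6), pan-neuronal (6.21), stress response (3.48), insulin (3.13), vulval signalling (3.10), pharynx (2.40) and germline (2.37) lists, and chemoreceptors were lower (0.191 times). Protein-coding genes as a class stood at 2.77 times under the same shifts, so the pharynx and germline lists were below the class. Listed regions were found at 37, 8 and 46 genes of the chemoreceptor, C-type lectin and F-box lists.

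Heterochronic genes, which time larval development, had peaks at 9 of 15 tested members. The 9 were lin-66 (signal 298), ain-1 (260), nhl-2 (248), lin-28 (244), lin-14 (170), dre-1 (129.4), lin-46 (129.1), alg-1 (124.2) and kin-20 (103), of which kin-20 ranked 4080 in replicate 1. This list alone was tested against genes of every class, of which 4676 of 14600 had a peak, although its matched members were all protein-coding (odds ratio 3.18, interval 1.13 to 8.95, exact adjusted p = 0.062). Against protein-coding genes, the background of the other lists, it stood at 1.95 (2978 of 6846 others, interval 0.69 to 5.48, exact adjusted p = 0.34). That background was added for this list after the data were seen. With it the list passed with replicate 1 alone (odds ratio 3.88, exact adjusted p = 0.038), with 2000 bp upstream (4.88, adjusted p = 0.027) and against all annotated protein-coding genes (7.33). It did not pass with replicate 2 alone (2.09), among the 2018 strongest peaks (3.48, exact adjusted p = 0.061), with 500 bp on either side (1.25) or with nearest starts (1.88). Against genes of every class the odds ratios in these settings were 6.21, 8.52 and 11.6, then 3.27, 4.99, 1.91 and 2.38, and the 2018 strongest peaks also passed (exact adjusted p = 0.020). With shifted peaks the list was higher (5.34 times). The 4 miRNA genes of the list that the annotation names with a prefix were not matched. When they were looked up after the data were seen, lin-4, mir-48 and mir-241 had a peak and mir-84 a weaker listed region. The windows of alg-2, sea-2, lin-41, lin-42, daf-12 and hbl-1 held only weaker listed regions, with ranks from 4247 (alg-2) to 8218 (hbl-1), and lin-29 had no listed region. Of the 6 Hox cluster genes none had a peak: lin-39 (rank 7348), nob-1 (rank 10855) and ceh-13 (rank 19110) had listed regions, and egl-5, mab-5 and php-3 had none. At the tagged gene itself, hmg-11 (chromosome II), no pooled region lay within 20 kb (1 region, not among the 4037 strongest, in each replicate's own list), and the stretch between the nearest listed summits ran from 4622563 to 4695064 (72.5 kb). Of 10000 random protein-coding genes, 14.2% had no pooled region within 20 kb, 30.9% had no peak within 20 kb and 16.6% lay in a stretch as long. The paralogue hmg-12 had a peak 450 bp upstream (chromosome II, 11915835 to 11916290, rank 1364), and unc-119, the gene mutated in the strain, had a peak 18 bp downstream of its start (chromosome III, 10906246 to 10906701, rank 3009).

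Genes of tRNAs and snoRNAs were at peaks more often than other genes, and genes of piRNAs less often. Of 388 tested tRNA genes, 242 (62.4%) had a peak, against 31.2% of other tested genes (odds ratio 3.65, interval 2.96 to 4.496), with a median summit position 25 bp upstream (−25 bp). Of 197 tested snoRNA genes, which guide modification of other RNAs, 58.9% had a peak (odds ratio 3.09, interval 2.32 to 4.11). Restricting the test to summits outside protein-coding windows, chosen after the data were seen, left 181 of 298 tRNA genes (odds ratio 8.96, interval 7.03 to 11.4) and 53 snoRNA genes with a peak (4.09, interval 2.83 to 5.91). Protein-coding genes as a class had an odds ratio of 2.75 (2987 of 6861). Genes of piRNAs (310 of 3455, odds ratio 0.153, interval 0.135 to 0.173) and pseudogenes (29 of 199, 0.358, interval 0.241 to 0.531) had peaks less often. These intervals treat genes as independent, although neighbouring genes share windows. With shifted peaks, which keep their spacing, piRNA genes stood at 0.450 times and pseudogenes at 0.299 times (permutation adjusted p = 0.037 and 0.0031). The class annotated as ncRNA had peaks at 912 of 3257 (0.78, exact adjusted p = 2.7e-08), a direction that turned against all annotated genes (1.25) and outside protein-coding windows (1.57). With shifted peaks it stood at 2.60 times, below the 2.77 times of protein-coding genes. Genes of snRNAs (13 of 37, odds ratio 1.15), miRNAs (44 of 120, 1.23), lncRNAs (26 of 74, 1.15) and antisense RNAs (6 of 27, 0.61) did not pass the threshold, and none of the 20 rRNA genes had a listed region. Genes of miRNAs were higher past the threshold outside protein-coding windows (31 of 86, odds ratio 2.81, interval 1.801 to 4.39), with 2000 bp upstream (1.56), against all annotated genes (1.83) and with shifted peaks (3.57 times). With shifted peaks lncRNAs (2.98 times) and snRNAs (2.25 times) were also higher, and with nearest starts antisense RNAs were lower (odds ratio 0.125).

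Peak summits were less A/T-rich than the other listed summits. Mean A+T content in the summit base and 50 bp on either side was 53.1% ± 8.1 (SD, 4037 peaks) for peaks and 63.6% ± 9.0 (SD, 25963 regions) for the others, a difference of −10.4 percentage points (bootstrap interval −10.7 to −10.2, permutation p = 1e-05, the smallest that 100000 resamples can give), and the genome had 64.6%. The difference was local: windows centred 500 bp to the left of the summit on the chromosome had 64.8% in peaks and 66.3% in the others. It was −9.3 points with replicate 1 alone and −10.1 points with replicate 2 alone. A+T content rose as signal fell, from 48.9% in the 1009 strongest peaks to 52.3% and 54.8% in the next groups of 1009 and 56.6% in the 1010 weakest.

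**Figure D4:**
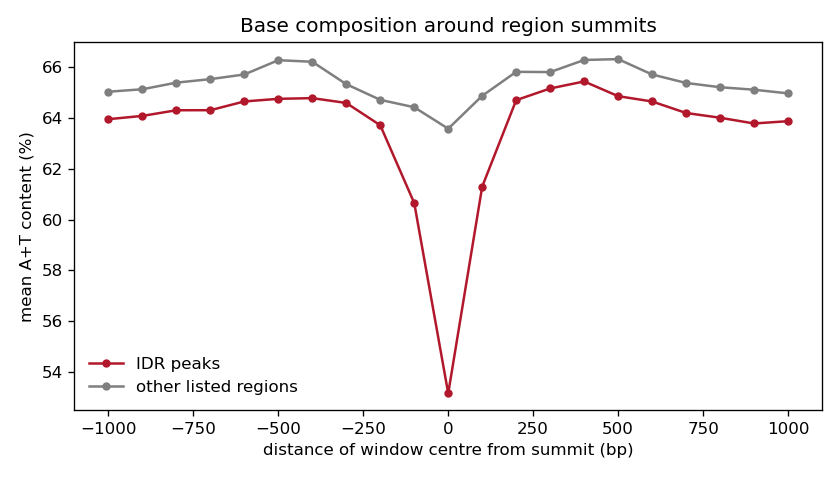
Mean A+T content (%, y axis) of windows centred at each distance from the summit (bp, x axis) for IDR peaks and the other listed regions of the pooled ce11 list. Peaks fall to 53.1% at the summit, against 63.6% for the others, and both lie near 65% at 500 bp.

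Motifs of the AT-hook type were less frequent at peaks than at the other listed regions. AATT was present in 44.2% of peak windows and 73.5% of the others, and stayed lower at matched A+T content (odds ratio 0.742, interval 0.686 to 0.802), as did AAATTT (9.0% and 27.7%, matched 0.732, interval 0.648 to 0.827). Within promoter windows alone neither passed at matched A+T (n = 3046 peaks, odds ratios 0.905 and 0.963, adjusted p = 0.090 and 0.67). AATATT, ATATAT and AAAAAAAA did not pass the threshold at matched A+T (n = 4037 peaks, odds ratios 1.05, 1.00 and 1.02, adjusted p = 0.71 to 0.98). A run of at least 8 A or T bases was in 34.8% of peaks and 65.6% of the others (odds ratio 0.279), and at matched A+T the direction turned (odds ratio 1.14, interval 1.04 to 1.24, n = 4037 peaks, adjusted p = 0.0071), a call lost with replicate 1 alone (1.07, adjusted p = 0.16), with the 2018 strongest peaks (1.09) and with 100 bp flanks (1.08). GAGAGAGA was in 7.8% of peaks and 2.0% of the others (matched odds ratio 2.39, interval 2.04 to 2.79). GCGCGC was in 7.1% and 1.4% (matched 2.17, interval 1.83 to 2.58). TGATAA, the GATA-factor site, was in 3.4% and 7.7% (matched 0.706, interval 0.588 to 0.849), and CACGTG, the E-box, in 2.4% and 2.0% (unmatched odds ratio 1.21, exact p = 0.11; matched 0.715, interval 0.565 to 0.906). The E-box no longer passed with 100 bp flanks (matched 0.880) or in promoter windows alone (0.844). Compared with dinucleotide-shuffled peak windows, peaks held GAGAGAGA 2.90 times as often, ATATAT 2.53, AATATT 1.85, GCGCGC 1.64, AAAAAAAA 1.46, a run of A or T 1.34, AAATTT 1.04, AATT 1.01, TGATAA 0.972 and CACGTG 0.897 times as often.

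The lists on the older build gave nearly the same picture. On ce10 there were 4030 IDR peaks with a median signal of 106.4, against 4037 and 106.1 on ce11, and signals of equal rank differed by at most 0.75%. On ce10 the strongest regions of the replicates overlapped in 78.7% of cases, and X had an odds ratio of 1.05.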

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

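The settings named nearest start only, protein-coding windows only, summits outside protein-coding windows, strata of distance to a start, and the backgrounds of protein-coding genes, with or without miRNA genes, for heterochronic genes were chosen after the data were seen, and the others before. Ribosomal protein genes kept more peaks than other genes in every setting run, with odds ratios from 4.91 (nearest start only) to 39.5 (all annotated genes), and the lower A+T content of peaks and their place upstream of starts kept direction and threshold in every setting. Each pair of a result and an alternative setting was counted. Of the pairs that answer a comparison, 76 kept direction and call, 16 moved, 8 reversed and 5 newly passed the threshold. Of those for single lists, classes, motifs and genes, 561 kept both, 52 reversed, 46 newly passed and 37 no longer passed. A call was also kept where neither value passed, and a reversal was counted whether or not either value passed. Among results past the threshold in the main setting, 1 reversed against all annotated genes, 2 with shifted peaks and 1 outside protein-coding windows. Where no cause is named, the cause was not tested. The strongest regions shared by the replicates were 74.7% with reciprocal overlap, 66.6% with summits within 100 bp and 76.0% with the stricter peaks, and the IDR peaks among the strongest of both were 71.8%, 66.7% and 98.3%; the overlap rules lower both shares by counting fewer pairs, and the stricter peaks keep the main overlap rule. With the stricter peaks, odds ratios were 0.965 for chromosome III, 0.973 for IV, 0.822 for other exons, 0.871 for miRNAs, 1.012 for bHLH and GATA factors and for vulval signalling, 0.910 for pharynx, 1.125 for chemoreceptors, 0.433 for C-type lectins and 1.102 for ATATAT, and 2 lists were lower. Against genome length ratios were 1.23 for chromosome I, 0.897 for II, 1.38 for III, 0.919 for IV, 0.648 for V and 1.09 for X. All of these were past the threshold by binomial test. On ce10 chromosome IV stood at 0.998. Against random positions other exons stood at 0.262. With 500 bp on either side of the start, odds ratios were 0.887 for other exons, 0.875 for histones, 1.46 for bHLH and GATA factors, 0.973 for insulin signalling, 0.911 for pharynx, 0.928 for F-box proteins and for stress response, and 0.684 for lncRNAs. With 2000 bp upstream they were 1.797 for bHLH and GATA factors, 1.05 for body wall muscle, 0.924 for pharynx and 0.905 for F-box proteins. Against all annotated genes they were 0.373 for histones, 1.57 for vulval signalling, 0.881 for germline, 1.11 for body wall muscle, 0.948 for pharynx, 0.314 for F-box proteins, 0.0952 for C-type lectins and 1.25 for ncRNAs, with 12 lists higher, 11 lower and 5 classes higher. With shifted peaks the ratios were 1.33 for antisense RNAs, 2.60 for ncRNAs, 0.360 for C-type lectins, 1.795 for bHLH and GATA factors, 2.26 for body wall muscle, 1.21 for detoxification, 1.29 for homeobox genes, 1.67 for nuclear hormone receptors and 3.10 for vulval signalling, with 17 lists higher, 1 lower and 7 classes higher. Protein-coding genes as a class stood at 2.77 in that setting, so a ratio over 1 there does not place a list above other genes. With the nearest start only they were 0.774 for lncRNAs, 0.469 for C-type lectins and 0.938 for F-box proteins, with 3 lists higher and 3 lower. Outside protein-coding windows ncRNAs stood at 1.57. AAAAAAAA stood at 0.974 with 100 bp flanks and 0.980 in promoter windows. Within 50 kb of hmg-11 there were 3 peaks, since the stretch is longer. Without one replicate, odds ratios ranged from 0.997 to 1.03 for chromosome I, from 0.991 to 1.06 for III, from 0.988 to 0.997 for IV, from 0.891 to 1.05 for other exons, from 0.595 to 0.703 for C-type lectins, from 1.005 to 1.39 for bHLH and GATA factors, from 0.923 to 1.45 for F-box proteins and from 1.04 to 1.14 for ATATAT. Read depth is unknown from the lists, so what it limits was not measured.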

Other observations

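The tests of GAGACGCAG and GCGCAGGG, gene families by symbol, X against the autosomes, narrow peaks, tRNA genes outside protein-coding windows, nearest starts and strata of distance were chosen only after the data were seen, and so was the test of composition bias by coding exons. A set of 6 sequences was tried together: GAGACGCAG and its part AGACGCAG, GCGCAGGG and its extension GCGCAGGGAG, CGCAGAGAG and GAGAGA. GAGACGCAG was assembled from the 6-base sequences most enriched in these same peaks, so its values describe that choice and are no independent test. It was present in 433 of 4037 peaks (10.7%, 95% Wilson interval 9.8 to 11.7) and 1.24% of the other listed regions (odds ratio at matched A+T 4.63, interval 3.93 to 5.45). Its peaks included those at lin-66, hmg-1.2, drap-1, ubc-3 and lin-40, of which ubc-3 and lin-40 were named after their values were seen. It was in 4 of the 68 peaks counted for ribosomal protein genes and in 0 of the 36 of translation factors and tRNA synthetases, and was most frequent at F-box and MATH-BTB proteins (5 of 21), nuclear hormone receptors (6 of 26) and stress response genes (3 of 17), among lists with at least 10 members at peaks. It was less frequent in peaks on X (6.6%) than in autosomal peaks (11.7%, odds ratio 0.529, interval 0.391 to 0.717), and also in the other listed regions of X (0.395%) than in those of autosomes (1.43%). At matched A+T its odds ratio in peaks over the other regions was 7.25 on X (interval 3.99 to 13.1) and 4.41 on autosomes (interval 3.72 to 5.24), a difference that was not tested.

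Among 56 gene families defined by symbol, 5 had peaks more often than other tested genes: rps (29 of 29), rpl (39 of 43), eif (18 of 21, translation initiation), taf (10 of 12, the general transcription factor TFIID) and vps (16 of 22, vesicle sorting). The 6 families with peaks less often were nlp (1 of 17), nhr (26 of 95), col (4 of 28), glb (0 of 11, globins), ttr (0 of 10, transthyretin-related) and lgc (1 of 13, ligand-gated channels). Peaks on X lay in protein-coding promoter windows less often than autosomal peaks (53.3% and 62.7%, odds ratio 0.678, interval 0.579 to 0.794). The share of annotated protein-coding genes with a peak was 23.03% on chromosome III, 20.9% on I and 9.1% on V, and among genes with a listed region it was 46.4%, 45.3% and 41.5%. Regions narrower than the usual 456 bp made up 151 peaks, had a median signal of 251 against 104.1 for the others, and were 66 of the 100 strongest.

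Peaks had a lower A+T content than the other listed regions, and among regions with 47.5 to 58.4% A+T, 16 of 1282 coding-exon regions and 1346 of 3497 promoter regions were peaks (odds ratio 0.0202, interval 0.0123 to 0.0332). Composition alone therefore did not decide which regions were peaks; the bound set before this value was seen took that to exclude a bias of the libraries for G/C-rich DNA, wrongly, since a bias can act among promoters, where the difference was −9.60 points. Promoter location as the whole cause is argued against, since in 4 strata of distance to a start the difference was at least −6.54 percentage points in size, and that stratum was the closest to the start. Composition bias, and a signal from open chromatin that any tagged protein would give, stay open, as no control library was analysed here, and no biological explanation was tested, since there is 1 group.

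Ribosomal protein and respiratory chain genes had peaks more often than other genes. For ribosomal protein genes, sharing of promoter windows with neighbours is argued against as the whole cause, since with each summit given to its nearest start the odds ratio was 4.91 (interval 2.51 to 9.58). It fell there from 22.5, and genes with a peak from 68 of 72 tested to 31 of 43, so sharing as a part of the cause stays open. For the respiratory chain sharing as the whole cause stays open, since the odds ratio fell from 5.88 to 1.88 (interval 0.81 to 4.35), with 22 genes tested in place of 33. Non-specific signal at highly transcribed loci may contribute to both, since tRNA genes, which another polymerase transcribes, had peaks more often outside protein-coding windows (odds ratio 8.96, interval 7.03 to 11.4). No expression values were used, and no biological explanation was tested.

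GCGCAGGG, the core of a motif known from sites on X that recruit the dosage compensation complex, was looked for because strong intergenic peaks lay on X, and was in 17 of 777 peaks on X and 3 of 3260 autosomal peaks (odds ratio 24.3, interval 7.10 to 83.1), and GCGCAGGGAG in 4 and 0. Peaks with it included the intergenic regions on X at 806573 to 806782, at 11094083 to 11094301 and, at −4836 bp from the start of xol-1, at 8036371 to 8036484, the last chosen after its values were seen. The sequence was 1.62 times as dense on X as on autosomes over the whole genome (interval 1.26 to 2.09), which argues against a higher frequency on X as the whole cause: 17 of 81 occurrences on X and 3 of 233 on autosomes lay at peaks. The lower A+T of X peaks as the whole cause is argued against by the ratio in strata of A+T (26.4, interval 7.27 to 96.1). These values are consistent with HMG-11 or general ChIP signal at such sites, which the data do not separate, and no biological explanation was tested.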
